A study of Mus musculus with 30 samples.

How the data were processed

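RNA of brain microvascular fragments had been measured on 30 Affymetrix mouse arrays. Per the labels, about 100 ng of total RNA, isolated with silica columns and DNase treatment, was amplified by the Affymetrix small-sample protocol to biotin-labelled cRNA. The deposited values are log2 signals made by the authors with GCRMA 2.6.0 under R 2.4.1, which corrects background by probe sequence, applies quantile normalization and summarises each probe set. They were used as deposited, with no further transformation, and all 30 value columns entered.

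The lowest value shared by the arrays showed that they had been normalized in 2 batches. The 24 arrays of the ret and R26P models share a lowest value of 2.16, which 35.8% to 37.0% of their values take, and the 6 wild-type arrays share 2.17, which 32.3% to 32.7% of their values take. Wild-type arrays were therefore compared only with each other. Tests of R26P controls against wild type in the 2 regions, and the use of wild type as the control of R26P mutants, were planned and not run, because genotype and batch cannot be separated.

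Of 45101 probe sets, 34958 were paired with exactly 1 gene by the array's annotation, 932 with several and 9211 with none; 34754 of the first had a gene identifier in the reference, and 0 symbols needed replacement. Of the 64 Affymetrix control probe sets, 13 are among those paired with 1 gene. The 18194 genes covered were each represented by the probe set with the highest mean over all arrays (9012 genes had more than 1). A gene was tested if that probe set was above 4 on the log2 scale in at least 3 arrays, which left 11243 genes. Sums of signal over an array carry no depth, and the number of arrays sets the precision.

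Groups were taken from the labels. Tests were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior), on the arrays of the compared groups alone, two-sided, with Benjamini-Hochberg adjustment over the genes tested. They compared ret mutants with ret controls, R26P mutants with R26P controls in each region, cerebellum with cerebrum in wild type, R26P controls and R26P mutants, the R26P effect between regions, and the ret effect with the R26P effect in cerebrum. A change is given as log2 change with its standard error, as a fold, or as group means with SD. Replicate numbers were not used as a block in the tests reported first. For the region comparisons the numbers do pair the arrays: after removal of group means, arrays of the same number correlated at 0.344 to 0.840 and each array fitted best with its own number, so values with the number as a block are given beside them. Between controls and mutants the numbers do not pair.

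Gene lists for cell types and pathways were written before the data were examined, and 26 of 30 had enough measured genes to test. They were tested with camera, which asks whether the genes of a list rank higher or lower than the other genes, with its preset correlation between genes of 0.01, and again with a correlation estimated from the data. The rotation test fry, which asks whether the genes of a list move one way on balance, was an alternative. In 6 lists in ret mutants, 2 in R26P cerebrum and 3 in R26P cerebellum, none past the threshold, the median and the mean differed in sign.

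Genes are named by a rule set before the data were examined. It takes the 10 largest falls and rises without overlap between groups in each mutant comparison, 6 each way in each region comparison and 5 each way in each test of a difference of effects. It adds up to 4 changed members of each list, or the 2 brightest where none changed, up to 20 shared genes, and a short set of genes fixed in advance for pericytes, barrier, sex and region. The text gives a selection of these. Prl, Cga and other genes marked as such were chosen after their values were seen.

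The procedure was tested on simulated data made from the arrays' own residual spread, over the same 11243 genes, with changes added to genes of mean signal above 6. At log2 changes of 0.5, 1, 2 and 4 it recovered 32%, 86%, 90% and 100% of changed genes in the ret design, 30%, 62%, 96% and 98% in R26P cerebrum and 28%, 78%, 98% and 100% in R26P cerebellum. False calls made up 4.94%, 2.05% and 3.18% of calls in those designs, 8.11% in the test between regions and 8.72% in that between models. A list shifted by −0.5 was the 1 list called of 26. Noise was drawn separately for each gene, whereas the genes of some lists moved together on the real arrays. The estimated correlation in ret mutants was 0.43 for the pericyte list and 0.03 for the leukocyte adhesion and activation list. The simulation therefore does not test the preset correlation of 0.01. Within groups the lowest correlation between arrays was 0.957, in ret mutants.

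Alternatives set before the data were examined were no expression filter, a stricter one (mean above 6), the mean of a gene's probe sets, all probe sets, an intensity trend with a robust prior, renewed quantile normalization, a fit of all 30 arrays, the replicate number as a block, the sex label as a covariate, other list tests and leaving out each array. Chosen after the data were seen were the mean of Gh, Prl and Cga as a covariate, leaving out arrays with Gh above 8, the level of Xist as a covariate, and leaving out each array for lists and correlations. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.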

Results

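Pericytes sit on the outer wall of brain capillaries, where they are recruited during development by platelet-derived growth factor B (PDGF-B) released from endothelial cells. Mice with too little PDGF-B at the vessel wall keep few of these cells, and the comparisons below ask which transcripts of brain vessels change when that happens. RNA of microvascular fragments, short lengths of vessel freed from brain tissue that hold endothelial cells with their attached mural cells, had been amplified and hybridised to 30 Affymetrix arrays. In the first model, both Pdgfb alleles lacked the retention motif that holds the protein near the cell surface (ret mutants, 4 arrays), and heterozygotes served as controls (ret controls, 4 arrays). The labels name no brain region. In the second model, mice without mouse Pdgfb carried a human PDGF-B transgene that Tie2-Cre switched on in endothelium (R26P mutants), and their controls kept mouse Pdgfb and a silent transgene. Cerebrum and cerebellum of this model gave 4 control and 4 mutant arrays each, and wild-type mice gave 3 arrays of each region. The labels call the arrays biological replicates, give ages of 8 to 10 months for ret controls and 7 to 10 months for ret mutants, and contradict each other for the R26P groups (1 year in some fields, 2 months in others). Wild-type mice were 2 months old. The number of arrays per group limits the precision of every comparison.

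Labels were checked against genes whose state the genotype, sex or region fixes. Mouse Pdgfb averaged 12.66 ± 0.17 log2 units (SD, n = 4) in control and 5.98 ± 1.58 in R26P mutant cerebrum, and 12.35 ± 0.20 against 5.53 ± 1.32 in cerebellum, so the R26P labels held on all 16 arrays. The highest mutant signals, 8.01 and 7.51 on the cerebrum and cerebellum arrays of number 3, lay above the background value of 4.73 but below every control. The ret allele is still transcribed, and Pdgfb stood at 11.85 ± 0.19 in ret controls and 12.17 ± 0.34 in ret mutants (adjusted p = 0.26), which checks nothing. Xist, made from the inactive X chromosome, and the Y-linked Eif2s3y matched the sex label on all arrays except the 4 of the ret controls. The 3 ret controls labelled male had Xist at 12.21, 12.68 and 12.27 with Eif2s3y at 2.16, and the 1 labelled female had Xist at 2.32 and Eif2s3y at 9.49, so the sex labels of this group were not relied on. Gabra6, a receptor subunit of cerebellar granule cells, averaged 4.77 in wild-type cerebellum against 2.61 in cerebrum (adjusted p = 0.0018), and 4.54 against 2.16 in R26P controls (adjusted p = 0.0087). Cerebrum is at or near the lowest value, so the direction was read and not the size. In R26P mutants it did not pass and read 3.85, 2.93, 2.21 and 3.14 in cerebellum 1 to 4, against 2.39 in cerebrum 3 and 2.16 in the other 3 cerebrum arrays. Along the 238 genes that differed between wild-type regions, a check chosen after values had been seen, 211 to 227 differed in the same direction in the R26P control pairs and 210, 201, 157 and 188 in mutant pairs 1 to 4. The median difference in that direction was 0.14 log2 units in mutant pair 3 and at least 0.47 in every other pair. Mutant cerebellum 3 was also the only cerebellar array with Gh above 8, so the region labels of mutant pair 3 are not settled. Mean signal of the pericyte list separated mutants from controls on every array: 9.45 to 9.91 in ret controls against 6.32 to 7.68 in ret mutants, and 10.43 to 11.16 in R26P controls against 6.81 to 8.74 in R26P mutants. Pericyte RNA is itself the outcome under study, so this is no independent check of the genotype labels. For the ret genotype no independent check was made.

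**Figure D1:**
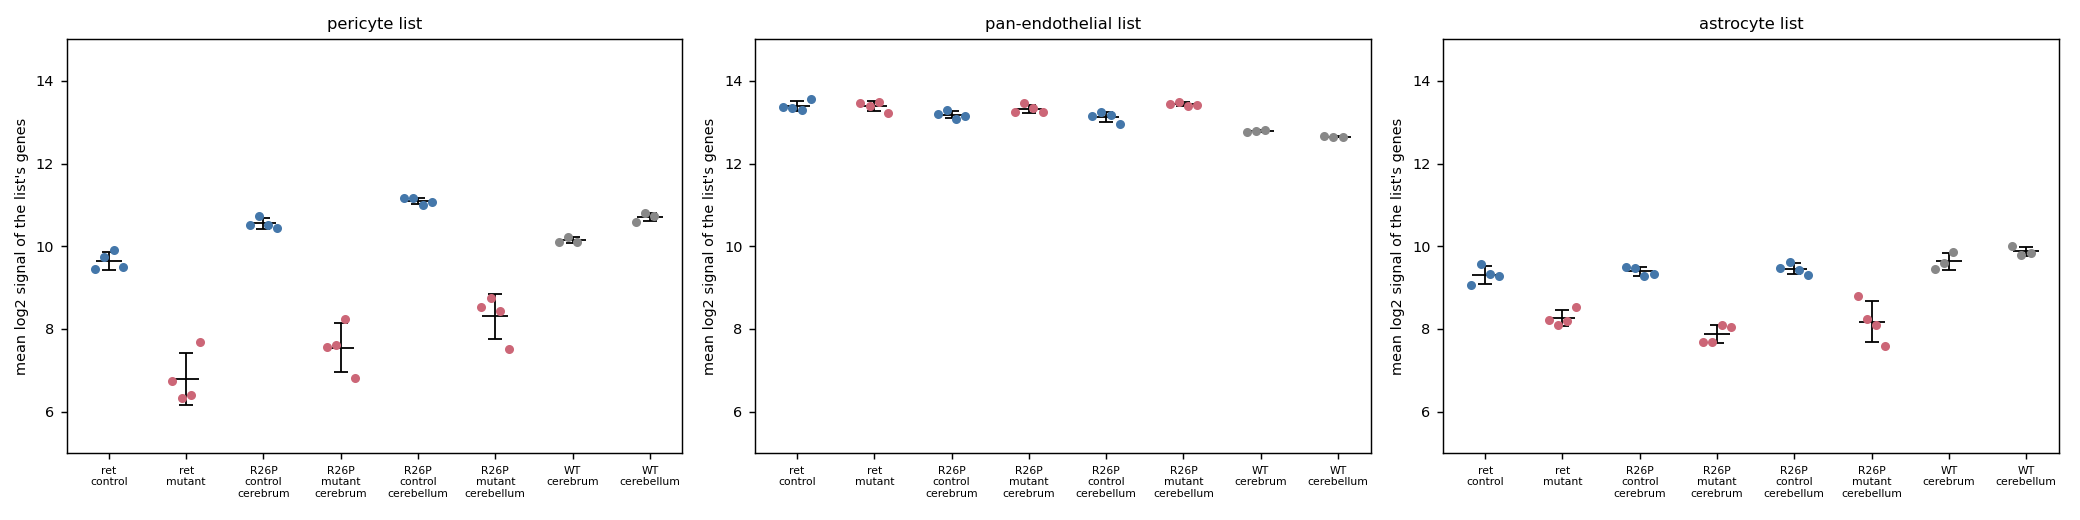
Mean log2 signal of the measured genes of 3 lists on each array (points), with the mean and SD of each group (bars). Wild-type arrays carry a different background level from the other 24 arrays and are shown for their 2 regions only.

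Vessel fragments of ret mutants had lost most of the RNA of pericyte genes. Of 23 measured pericyte list genes, 20 fell and 3 did not pass (22 fell and 1 rose when adjusted over the list alone), with a median log2 change of −3.15. Atp13a5, a cation-transporting ATPase, fell 91.4-fold (log2 change −6.51 ± 0.29 (SE), adjusted p = 2.7e-05). Its mutant signals of 3.22 to 4.58 lie close to the background, so this size depends on the background correction. The potassium channel parts Abcc9 and Kcnj8 fell 31.2-fold and 14.7-fold, the PDGF-B receptor Pdgfrb fell 9.82-fold (adjusted p = 3.2e-04). The surface proteoglycan Cspg4 fell 15.9-fold and the signalling regulator Rgs5 fell 5.63-fold. Part of this list was drawn from earlier work on PDGF-B-deficient mice, so the direction is not independent evidence. The list gave a camera adjusted p of 1.2e-17 with the preset correlation of 0.01 and an adjusted p = 0.305 with an estimated correlation. Lama2, a laminin chain of the vessel's basement membrane, fell 22.9-fold and Grm3, a glutamate receptor, fell 18.2-fold, both to mutant signals near the lowest value, so these sizes depend on the background correction.

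Other cells of the vessel wall and its surroundings shifted as well. Among 16 measured smooth muscle genes 4 fell and Synpo2 rose 2.61-fold (12 fell and 1 rose when adjusted over the list alone), with a camera adjusted p of 0.0013 and an adjusted p = 0.691 with an estimated correlation. Of 15 Notch genes 6 fell and 1 rose (7 and 1 over the list alone, camera adjusted p = 0.0013, or adjusted p = 0.305 with an estimated correlation), among them Notch3, the Notch receptor of mural cells (9.64-fold), the ligand Dll1 (3.45-fold) and the Notch target Hey2 (2.34-fold). Notch3 is also in the pericyte list, so the Notch call partly repeats the pericyte fall. Astrocyte end-feet partly stay on isolated vessels, and of 15 astrocyte genes 10 fell and none rose (11 over the list alone), with a median log2 change of −1.22. The glutamate transporter Slc1a2 fell 3.50-fold and the end-foot protein Mlc1 fell 3.09-fold (list: camera adjusted p = 1.9e-06, or adjusted p = 0.305 with an estimated correlation). The neuron list did not pass (median 0.40, adjusted p = 0.828) and neither did the oligodendrocyte list (median −0.11, adjusted p = 0.099). The microglia and macrophage list rose (1 of 19 genes, also 1 over the list alone, median 0.56; adjusted p = 0.0123), led by the lysozyme gene Lyz2 at 6.23-fold, with an adjusted p = 0.76 with an estimated correlation. Its adjusted p was 0.0648 without ret mutant array 4.

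Endothelial genes of ret mutants changed in both directions. The pan-endothelial list had a median log2 change of −0.06 (2 of 20 rose, 4 fell; adjusted p = 0.828), with the TGF-beta co-receptor Eng up 1.92-fold and the VEGF receptor Flt1 down 1.54-fold. Of 23 barrier transporter genes 6 fell and none rose (11 over the list alone): the lipid transporter Mfsd2a, which restrains transcytosis, fell 5.45-fold (adjusted p = 2.6e-05), the transferrin receptor Tfrc 2.97-fold and the amino acid transporter Slc38a3 2.87-fold. This list had a camera adjusted p of 0.0056, an adjusted p = 0.691 with an estimated correlation, and 0.06 without ret mutant array 4. The glucose transporter Slc2a1 (log2 change −0.10, adjusted p = 0.28) and the junction protein Cldn5 (0.16, adjusted p = 0.35) did not pass. In the leukocyte adhesion and activation list 4 of 15 genes rose (4 over the list alone), including the chemokines Cxcl10 (3.48-fold) and Ccl5 (from 2.71, its background value on all 4 controls, to a mean of 4.36). Transcripts of blood leukocytes, a set chosen after values had been seen, were higher on the same arrays (10 of 13 measured genes, median log2 change 2.72), as was Lyz2. Plac8 rose by 5.90 from near the lowest value. The cells behind the leukocyte adhesion and activation list are therefore not known. That list's camera adjusted p was 0.0482, with an adjusted p = 0.305 with an estimated correlation, and it did not pass without ret control 2 (0.101) or 4 (0.0769) or ret mutant 1 (0.0894) or 3 (0.0529).

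Some genes of vessel growth and of TGF-beta signalling rose in ret mutants, although neither list passed camera. Both passed the alternative test fry (adjusted p = 4.9e-05 for sprouting and 1.4e-05 for TGF-beta and BMP). Angpt2, a Tie2 ligand released by sprouting endothelium, rose 10.2-fold (10.14 ± 0.19 to 13.49 ± 0.51; adjusted p = 3.2e-04), the tip-cell peptide Apln 16.5-fold and the vasoactive peptide Adm 9.52-fold. As a group, 7 of 14 sprouting genes rose and 2 fell (camera adjusted p = 0.067), so the list did not pass camera. It passed without ret control 3, at 0.0341, and without ret mutant 3, at 0.0301. Bmp6 rose 30.9-fold and the TGF-beta target Ccn2 rose 6.43-fold in a list that did not pass camera (adjusted p = 0.202). Large rises included Gh, Fgfbp1 (560-fold), which frees stored fibroblast growth factor, the anion transporter Slco1a5 (94.6-fold), the cadherin Cdh26 (85.7-fold) and the pigment-cell receptor Gpr143 (64.3-fold). Apart from Cdh26, the control means of these genes lie near the lowest values of the arrays, so the sizes depend on the background correction. Gh, the pituitary growth hormone gene, read 14.90, 13.68 and 15.23 in ret mutants 1, 2 and 4 but 2.84 in ret mutant 3 (adjusted p = 0.047), and its call was lost when any array other than ret mutant 3 was left out (largest adjusted p = 0.113). Plvap, a protein of leaky endothelium that is also present in pituitary vessels, followed the same 3 arrays, with 10.94 ± 0.05 in controls, 12.08 ± 1.15 in mutants and an adjusted p of 0.17. It passed without ret mutant 3 (adjusted p = 0.0018).

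**Figure D2:**
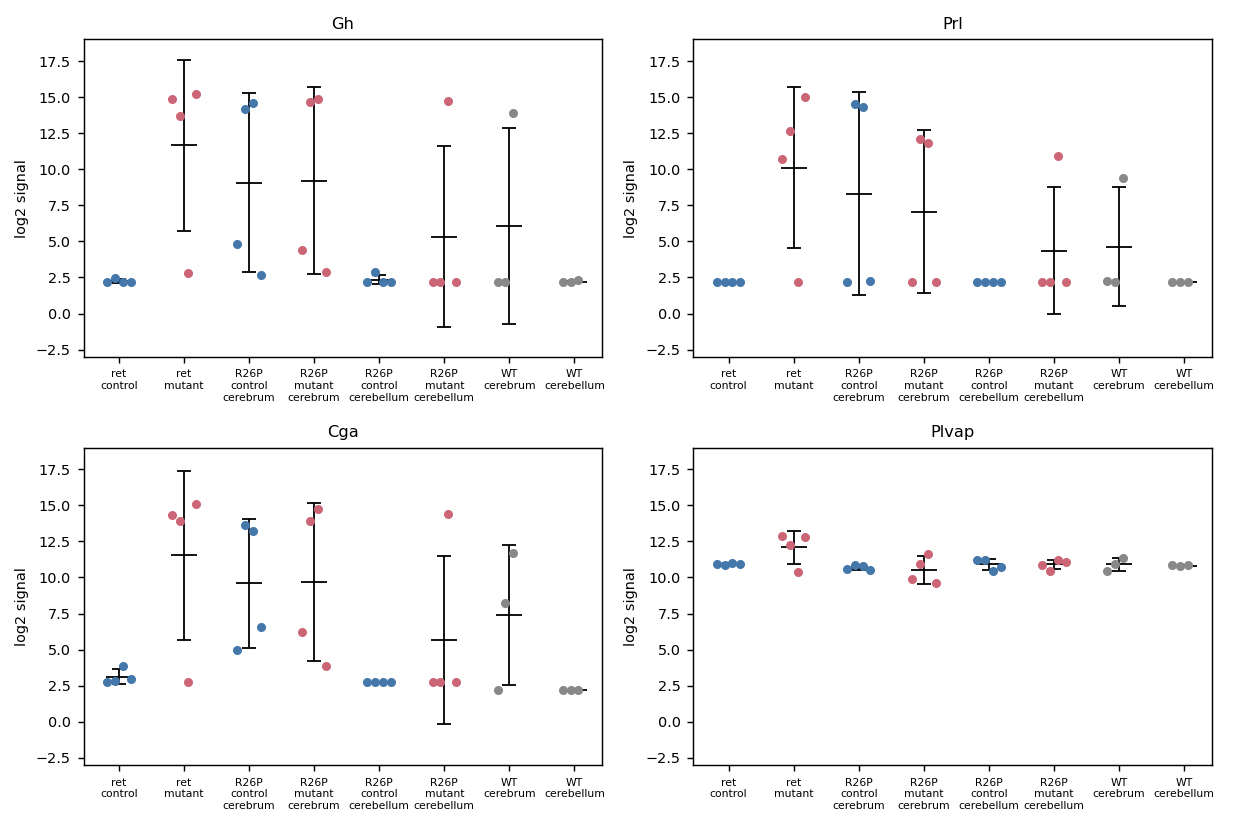
Log2 signal of 3 pituitary hormone genes and of Plvap on each array, with group means and SD. The hormone genes were chosen after the values had been seen.

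The limma test was run on the brightest probe set of each of 11243 genes, at an adjusted p below 0.05. In ret mutants 1870 genes changed (900 higher, 970 lower), 702 of them at least 2-fold, and 23.5% of genes did not overlap between the 2 groups where chance gives 2.86%. The other 19 lists tested had camera adjusted p values of 0.067 or more, and among them the perivascular fibroblast list passed without ret mutant 4 (0.0343). The count was 1153 without ret control 2, 892 with pituitary transcripts as a covariate, 919 without the arrays holding them (which leaves 1 mutant against 4 controls), 1051 with the sex label as a covariate (which Xist contradicts on the 4 controls), 1744 with the Xist level instead (chosen after the results had been seen) and 1229 without the expression filter.

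R26P mutants lost pericyte RNA in the cerebrum, and smooth muscle RNA with it. Of 23 pericyte genes 21 fell (21 over the list alone), with a median log2 change of −3.02 (camera adjusted p = 4.4e-19, or adjusted p = 0.169 with an estimated correlation). The phospholipase gene Pla1a fell 48.8-fold (log2 change −5.61 ± 0.14 (SE)), Grm3 57.7-fold, Abcc9 28.2-fold, Kcnj8 25.6-fold, Pdgfrb 7.40-fold and Cspg4 12.5-fold. Pdgfb itself fell (adjusted p = 7.9e-04), to 4.73, its background value, on mutant arrays 1 and 4. The mutant signals of Pla1a and Grm3 also lie near the lowest value, so the sizes of these 3 falls depend on the background correction. Among 16 smooth muscle genes 14 fell (14 fell and 1 rose over the list alone). They include the sarcomere gene Ldb3 (7.43-fold) and the calcium pump regulator Pln (5.08-fold). That list's camera adjusted p was 4.7e-08, with an adjusted p = 0.332 with an estimated correlation. PDGF signalling genes fell (5 of 8 lower, 1 higher, 6 and 1 over the list alone, camera adjusted p = 0.0054, or adjusted p = 0.169 with an estimated correlation), a list that holds the deleted gene. Notch genes fell (5 of 15 lower, 1 higher, the same over the list alone, camera adjusted p = 0.0192, or adjusted p = 0.169 with an estimated correlation), led by the Notch target Heyl (8.47-fold) and Notch3 (5.32-fold). Heyl and Notch3, and Pdgfrb of the PDGF list, are also in the pericyte list, so both calls partly repeat the pericyte fall.

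Several lists of cells around the vessels fell in R26P mutant cerebrum, while the oligodendrocyte list did not pass (1 of 8 lower, median −0.02, adjusted p = 0.992). Of 15 astrocyte genes 11 fell and 1 rose (12 and 1 over the list alone, median −1.49, camera adjusted p = 8.4e-08, or adjusted p = 0.169 with an estimated correlation): Mlc1 13.2-fold, Slc1a2 6.13-fold and the glycolytic enzyme Aldoc 5.24-fold. Of 15 perivascular fibroblast genes 7 fell and 1 rose (10 and 1 over the list alone, camera adjusted p = 0.0023, or adjusted p = 0.534 with an estimated correlation), among them the transporter Slc6a13 (5.47-fold). Neuron genes fell (3 of 10, 6 lower and 1 higher over the list alone, camera adjusted p = 0.0245, or adjusted p = 0.48 with an estimated correlation), with the dendrite protein Map2 down 6.63-fold. Choroid plexus and ependyma genes fell (2 of 11, 5 over the list alone, median −1.28, camera adjusted p = 0.0163, or adjusted p = 0.616 with an estimated correlation). Microglia and macrophage genes fell, while they rose in ret mutants, a difference that was not tested (3 of 19, 0 over the list alone, median −0.65, camera adjusted p = 0.0245, or adjusted p = 0.635 with an estimated correlation). That call was lost without control 3 (0.0787) or 4 (0.0517) or mutant 1 (0.0616) or 3 (0.102). Immediate early and heat shock genes fell (2 of 14, 0 over the list alone, median −0.69, camera adjusted p = 0.0054, or adjusted p = 0.587 with an estimated correlation).

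Several lists of endothelial genes rose in R26P mutant cerebrum. A higher share of endothelial RNA after the loss of mural RNA was not excluded as a cause. The pan-endothelial list had 7 of 20 genes higher and 2 lower (8 and 2 over the list alone, median 0.18, camera adjusted p = 0.0354, or adjusted p = 0.616 with an estimated correlation), with Eng up 2.04-fold and Flt1 down 1.62-fold. It did not pass without control 3 (0.0787) or 4 (0.0517) or mutant 2 (0.0661) or 3 (0.0617). Arterial genes rose (5 of 16 higher, 1 lower, 8 and 2 over the list alone, camera adjusted p = 0.0302, or adjusted p = 0.243 with an estimated correlation). The vasoconstrictor gene Edn1 (6.61-fold) and the kinase Bmx (3.53-fold) led it, and the call was lost without control 4 (0.0517) or mutant 3 (0.0613). TGF-beta and BMP genes rose (5 of 17 higher, 2 lower, 6 and 4 over the list alone, camera adjusted p = 0.035, or adjusted p = 0.48 with an estimated correlation). Bmp6 was up 20.6-fold and the inhibitory Smad6 up 4.85-fold, and the list call was lost without control 3 (0.0604) or 4 (0.0517) or mutant 3 (0.0613) or 4 (0.11). Barrier transporters fell (8 of 23 lower, 1 higher, 9 and 2 over the list alone, camera adjusted p = 0.035, or adjusted p = 0.616 with an estimated correlation). The lactate transporter Slc16a1 fell 3.55-fold, and the list did not pass without control 2 (0.0683), 3 (0.0585) or 4 (0.0517). Mfsd2a fell 2.84-fold (adjusted p = 0.036), a call lost without any of the 4 controls or mutant 2 (up to 0.091). The interferon list rose (2 of 12, 4 over the list alone, camera adjusted p = 0.0302, or adjusted p = 0.535 with an estimated correlation), with the GTPase Gbp2 up 1.61-fold. Its adjusted p was 0.0585 without control 3, 0.0535 without mutant 3 and 0.11 without mutant 4. The leukocyte adhesion and activation list rose (3 of 15, 3 over the list alone, camera adjusted p = 0.038, or adjusted p = 0.616 with an estimated correlation). It did not pass without control 1 (0.0818), 2 (0.0627) or 4 (0.0517) or mutant 3 (0.0617) or 4 (0.226). Mutant cerebrum 4 stood apart, with a list mean of 10.56 against 9.15 to 9.45 in the other 3 mutants. Blood leukocyte transcripts, the set chosen after values had been seen, were higher here too (6 of 13 measured genes higher, 1 lower, Plac8 by 5.16), so the cells behind this list are not known.

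Sprouting genes did not pass camera as a list in R26P mutant cerebrum (5 of 14 higher, 2 lower, adjusted p = 0.0871), but passed fry (adjusted p = 1.4e-04). Several lists that camera called here did not pass fry. They were pan-endothelial (fry adjusted p = 0.061), barrier transporters (0.0943), interferon (0.053) and leukocyte adhesion and activation (0.129). Neuron (0.0579), microglia and macrophage (0.232), choroid plexus and ependyma (0.0951) and immediate early and heat shock (0.0873) did not pass fry either. Angpt2 rose 8.50-fold (9.63 ± 0.28 to 12.71 ± 0.11, adjusted p = 2.3e-05) and Apln 26.3-fold. Other rises included Cdh26 (215-fold), Fgfbp1 (184-fold), Gpr143 (80.4-fold), the ectoenzyme Bst1 (58.2-fold) and Slco1a5 (37.7-fold). Of these Fgfbp1, Gpr143 and Bst1 start from control means near the lowest values. Plvap (log2 change −0.17, adjusted p = 0.81) and Cldn5 (0.17, adjusted p = 0.19) did not pass. In all, 2097 genes changed (939 higher, 1158 lower), 819 at least 2-fold, of which 589 were lower, and 25.9% did not overlap against 2.86% by chance. The count was 1387 without control 1, 1390 without the expression filter and 237 without the 4 arrays holding pituitary transcripts, which leaves 2 against 2. Without control 4 or without mutant 3, 10 lists passed instead of 16. The other 10 lists had adjusted p values of 0.0871 or more.

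**Figure D3:**
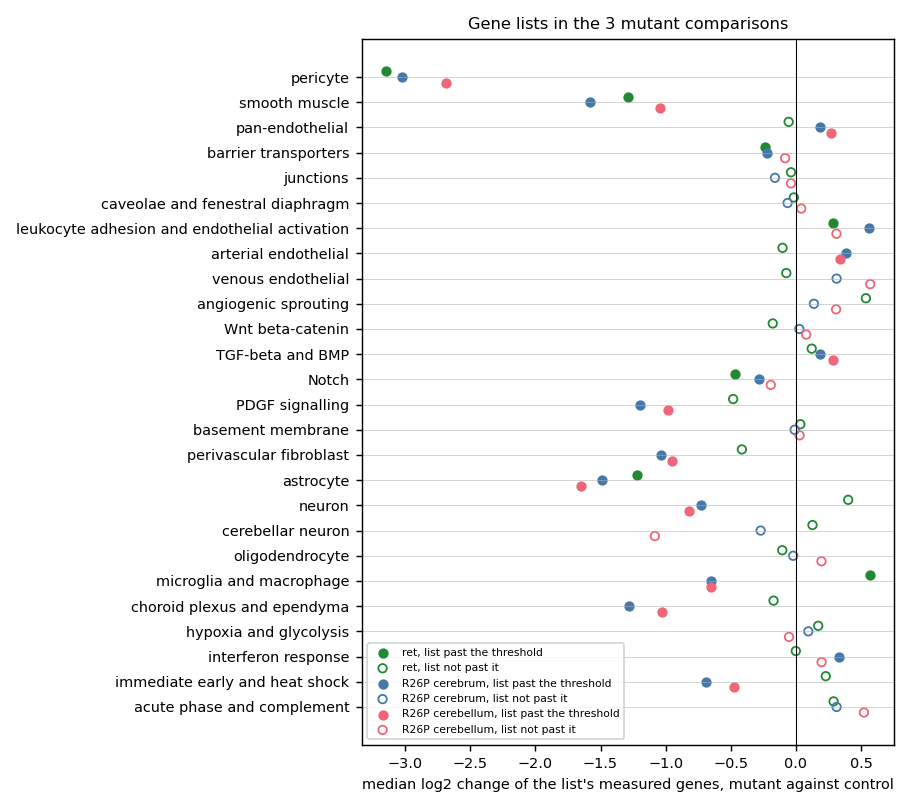
Median log2 change of the measured genes of each list in the 3 mutant comparisons. Filled points passed camera with the preset correlation at an adjusted p below 0.05, and none passed with an estimated correlation.

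In the cerebellum of R26P mutants most of the lists that fell in the cerebrum passed again, but the Notch list (adjusted p = 0.173) and the barrier transporters (adjusted p = 0.202) did not. Pericyte genes fell (21 of 23, the same over the list alone, median −2.68, camera adjusted p = 3.7e-19, or adjusted p = 0.326 with an estimated correlation), with Pla1a down 74.8-fold, Kcnj8 24.4-fold, Abcc9 21.4-fold, Cspg4 7.89-fold and Pdgfrb 6.43-fold. The mutant signal of Pla1a lies near the lowest value, so the size depends on the background correction. Pdgfb fell as well, to its background value of 4.73 on mutant array 1. Smooth muscle genes fell (7 of 16, 12 lower and 1 higher over the list alone, camera adjusted p = 1.8e-04, or adjusted p = 0.457 with an estimated correlation), including Ldb3 (4.12-fold) and Pln (3.08-fold). PDGF signalling genes fell (5 of 8 lower, 1 higher, 6 and 1 over the list alone, camera adjusted p = 0.0024, or adjusted p = 0.326 with an estimated correlation), with the receptor Pdgfra down 2.58-fold. This list holds the deleted gene and shares Pdgfrb with the pericyte list. Perivascular fibroblast genes fell (6 of 15 lower, 1 higher, 10 and 1 over the list alone, camera adjusted p = 3.9e-04, or adjusted p = 0.433 with an estimated correlation), among them Slc6a13 (5.13-fold) and the complement inhibitor Serping1 (2.46-fold). Astrocyte genes fell (9 of 15 lower, 1 higher, 11 and 1 over the list alone, median −1.65, camera adjusted p = 1.8e-04, or adjusted p = 0.407 with an estimated correlation), with the end-foot water channel Aqp4 down 5.48-fold. Neuron genes fell (3 of 10, 5 over the list alone, camera adjusted p = 0.0234, or adjusted p = 0.392 with an estimated correlation), with Map2 down 7.54-fold. Their adjusted p was 0.0565 without control 3. Microglia and macrophage genes fell (2 of 19, the same over the list alone, camera adjusted p = 0.0039, or adjusted p = 0.6 with an estimated correlation), among them the perivascular macrophage receptor Cd163 (4.37-fold). The mutant signals of Cd163 lie at or near the lowest value, so this size depends on the background correction.

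Part of the endothelial genes rose in R26P mutant cerebellum, where a higher share of endothelial RNA was not excluded as a cause either. The pan-endothelial list had 8 of 20 genes higher, none lower and 12 that did not pass (10 and 1 over the list alone, median 0.27, camera adjusted p = 2.4e-04, or adjusted p = 0.433 with an estimated correlation), with Eng up 2.37-fold. Arterial genes rose (7 of 16, 8 over the list alone, camera adjusted p = 9.5e-04, or adjusted p = 0.407 with an estimated correlation), led by Edn1 (9.05-fold) and Bmx (3.78-fold). TGF-beta and BMP genes rose (6 of 17 higher, 1 lower, 7 and 2 over the list alone, camera adjusted p = 0.0089, or adjusted p = 0.457 with an estimated correlation), led by Bmp6 (10.4-fold) and Smad6 (4.84-fold). Choroid plexus and ependyma genes fell (1 of 11, 0 over the list alone, camera adjusted p = 0.0089, or adjusted p = 0.6 with an estimated correlation), as did immediate early and heat shock genes (1 of 14, 0 over the list alone, camera adjusted p = 0.0016, or adjusted p = 0.486 with an estimated correlation). Angpt2 rose 6.82-fold (9.48 ± 0.35 to 12.25 ± 0.26; adjusted p = 1.9e-04), and other rises included Cdh26 (124-fold), Fgfbp1 (100-fold) and Gpr143 (59.6-fold). The control means of Fgfbp1 (3.06) and Gpr143 (2.29) lie near the lowest value, so these sizes depend on the background correction. Mfsd2a did not pass here (log2 change −0.76, adjusted p = 0.11), and neither did its difference from the cerebrum (0.75, adjusted p = 1). Cldn5 (0.17, adjusted p = 0.11) and Plvap (−0.01, adjusted p = 0.99) did not pass. In all, 1758 genes changed (780 higher, 978 lower), 707 at least 2-fold, and 22.8% did not overlap against 2.86% by chance. The count was 1143 without control 1, 1117 without mutant 3, 1081 without the expression filter and 1133 with pituitary transcripts as a covariate. The other 14 lists had adjusted p values of 0.0632 or more. Single arrays brought some of them past the threshold: leukocyte adhesion and activation without control 3 (0.0328) or mutant 1 (0.031) or 2 (0.0328), venous endothelial without control 3 (0.0328), cerebellar neuron without control 2 (0.0276) and interferon without mutant 3 (0.0452).

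Many genes changed the same way in the 2 models. In all 3 comparisons 227 genes were higher and 319 lower. The 2 R26P regions are paired by number and already share 493 higher and 763 lower genes, and a ret list independent of those would share 39.5 and 65.8 of them. Shared rises included Fgfbp1 (mean log2 change over the 3 comparisons 7.77), Cdh26 (7.04), Gpr143 (6.08), Slco1a5, Bst1, the lactate receptor Hcar1, the matrix protein Ltbp2, Apln, Bmp6 and the monocyte receptor Treml4. Control means of Fgfbp1, Gpr143, Hcar1 and Treml4, of Bst1 in R26P and of Ltbp2 in R26P cerebellum lie near the lowest value. Shared genes were picked in order of mean change, and for these genes size and place in that order are set by the background. The Treml4 call in cerebellum (adjusted p = 0.045) was lost without any array other than mutant cerebellum 2 (up to 0.112). Shared falls included Atp13a5 (−5.70), Abcc9 (−4.73), Kcnj8 (−4.39), Lama2 and the pericyte surface protein Cd248. They also included the uncharacterised 5033404E19Rik, Pla1a and Grm3, whose mutant signals lie at or near the lowest value. The size of these 3 falls, and so their place in that order, is set by the control level. Steap4, a metalloreductase, fell 6.91-fold, 6.31-fold and 7.77-fold in ret, cerebrum and cerebellum, and Angpt2 rose in each. Log2 changes of ret mutants correlated with those of R26P mutants at r = 0.584 in cerebrum and r = 0.524 in cerebellum across the 11243 genes (Spearman 0.417 and 0.333; genes are not independent replicates), and 13 of 794 and 23 of 637 genes called in both had opposite signs. The 2 regions of R26P mutants correlated at r = 0.911 (Spearman 0.860) with 0 of 1256 opposite signs, but the array numbers pair the regions as if taken from the same animals. Leaving out single arrays moved the shared count between 397 and 651, and it was 279 without the expression filter.

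**Figure D4:**
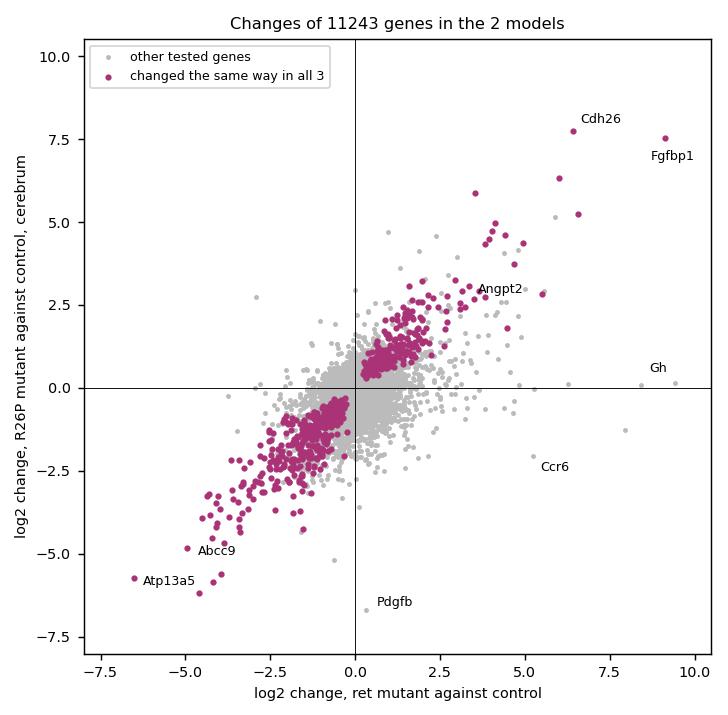
Log2 change of each tested gene in ret mutants and in R26P mutant cerebrum. Genes that changed in the same direction in all 3 mutant comparisons are coloured.

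**Figure D5:**
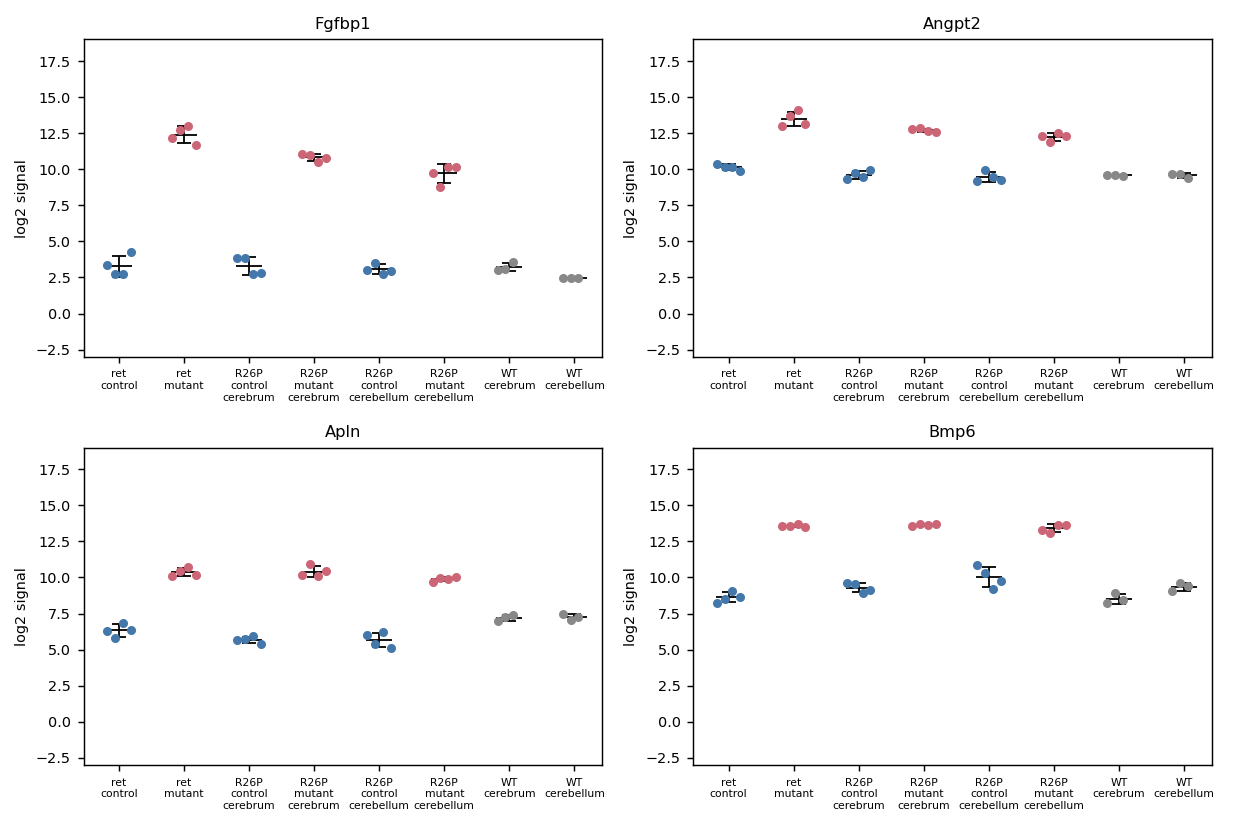
Log2 signal of 4 genes that rose in all 3 mutant comparisons on each array, with group means and SD.

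The test of a different R26P effect in the 2 regions passed for few genes. Alx1, a homeobox gene, stood at 5.21 ± 0.76 in control cerebrum and at 2.32 ± 0.08 in mutant cerebrum, against 2.17 in both cerebellar groups, where no fall could show (difference of log2 changes 2.89 ± 0.36 (SE); adjusted p = 0.0026). Ebf2, a transcription factor, did the reverse, falling from 5.20 ± 0.62 to 2.18 ± 0.04 in cerebellum (difference −2.57 ± 0.37; adjusted p = 0.013). The sialyltransferase gene St6galnac5 (difference 2.12, adjusted p = 8.9e-05) and the noncoding RNA Pantr1 (1.77, adjusted p = 0.0026) differed in the direction of Alx1, and the ganglioside synthase gene St8sia1 (−1.67, adjusted p = 0.0026) in that of Ebf2. In the region without the fall, controls of Alx1, Ebf2, St6galnac5 and St8sia1 already lay at or near the lowest value, so the calls do not show that the genotype acts in 1 region alone. Pantr1 read 4.17 to 4.37 in control cerebellum, and 4.37 recurs on mutant arrays, so it may lie near background there too. These 5 calls held whichever array was left out. The difference of differences passed for 13 genes (8 higher, 5 lower), and for 45 with the array number as a block, which includes all 13. The count was 7 without control cerebellum 2, mutant cerebrum 1 or mutant cerebellum 1, 6 without mutant cerebrum 2, 8 without mutant cerebrum 4. It was 0 with a stricter expression filter, 4 with the mean of probe sets, 6 without the expression filter and 7 without the arrays holding pituitary transcripts.

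The 2 models also differed in some genes when the ret change was set against the R26P change in cerebrum. Pdgfb, which by the labels only the R26P mutants lack, gave a difference of 7.00 ± 0.76 (SE, adjusted p = 8.1e-04). Mutant cerebrum 2 and 3 still read 6.45 and 8.01, above the background value of 4.73. Mmrn1, a multimerin of endothelium and platelets, rose from 2.18 to 7.00 ± 1.13 in ret mutants and stood at 2.34 and 2.43 in R26P control and mutant cerebrum (difference 4.73 ± 0.55, adjusted p = 8.1e-04). All groups but the ret mutants lie at or near the lowest value, so this size depends on the background correction. Dcdc2a, a microtubule-binding protein, rose from 5.82 to 8.12 in ret mutants and fell from 7.65 to 6.32 in R26P mutants (difference 3.63 ± 0.42; adjusted p = 8.1e-04), and the carboxypeptidase-like Cpxm2 differed by 3.56 (adjusted p = 0.024). These 4 calls held whichever array was left out, whereas that of the chemokine receptor Ccr6 (difference 7.31, adjusted p = 0.041) was lost without ret controls 1 to 3, ret mutants 2 or 4, control cerebrum 2 or mutant cerebrum 1 to 3 (up to 0.0872). In all 377 genes differed (188 higher, 189 lower). The labels give the models different genetic backgrounds, name no brain part for ret and contradict each other on the age of R26P mice, so no cause can be assigned. The count was 127 without ret control 1, 224 without ret control 2, 250 and 212 without ret mutants 2 and 4, 226, 226 and 243 without control cerebrum 1, 2 and 3, and 181 and 611 without mutant cerebrum 1 and 4. It was 102 with pituitary transcripts as a covariate, 130 without the arrays holding them (which leaves 1 ret mutant) and 177 without the expression filter.

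Wild-type vessel fragments of cerebellum and cerebrum differed in genes of mural cells and of the surrounding tissue. Pericyte genes were higher in cerebellum (7 of 23, 16 over the list alone, median 0.46, camera adjusted p = 8.6e-13, or adjusted p = 0.161 with an estimated correlation), as were perivascular fibroblast genes (3 of 15, 8 over the list alone, median 0.40, camera adjusted p = 8.2e-09, or adjusted p = 0.161 with an estimated correlation). Choroid plexus and ependyma genes were higher (2 of 11, 10 over the list alone, median 1.05, camera adjusted p = 6.6e-10, or adjusted p = 0.359 with an estimated correlation), as were cerebellar neuron genes (3 of 6, 3 over the list alone, camera adjusted p = 0.0026, or adjusted p = 0.161 with an estimated correlation). Immediate early and heat shock genes, which respond to tissue handling, were higher too (6 of 14, 11 over the list alone, median 0.78, camera adjusted p = 6.0e-14, or adjusted p = 0.134 with an estimated correlation). Pan-endothelial genes were lower as a group (0 of 20 past the threshold alone, 0 over the list alone, median −0.13, camera adjusted p = 0.0030, or adjusted p = 0.161 with an estimated correlation). Single genes included the chemokine Cxcl2 (16.1-fold higher in cerebellum, adjusted p = 0.0018), the glutamate receptor Gria4 (6.97-fold, adjusted p = 0.0052) and the laminin chain Lamb1 (2.67-fold, adjusted p = 0.005), and the neuritin gene Nrn1 was 5.44-fold lower (adjusted p = 0.0018). The lower groups of Cxcl2, Gria4 and Nrn1 lie at or near the lowest value of their probe sets, so these 3 sizes depend on the background correction.

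Further wild-type list calls rested on few arrays. Smooth muscle genes were higher in cerebellum (0 of 16, 1 over the list alone, camera adjusted p = 0.0053, or adjusted p = 0.585 with an estimated correlation). Their adjusted p was 0.0708 without cerebrum 3 and 0.119 without cerebellum 3. Basement membrane genes were higher (2 of 17, 2 over the list alone, camera adjusted p = 0.0099, or adjusted p = 0.585 with an estimated correlation), and their adjusted p was 0.0921 without cerebellum 1 and 0.054 without cerebrum 3. Astrocyte genes were higher (3 of 15, 5 higher and 2 lower over the list alone, camera adjusted p = 0.0397, or adjusted p = 0.585 with an estimated correlation), and their adjusted p was 0.0705 with the array number as a block, 0.125 and 0.0608 without cerebrum 1 and 2 and 0.252 without cerebellum 1. Barrier transporters were lower (0 of 23, 0 over the list alone, camera adjusted p = 0.0327, or adjusted p = 0.585 with an estimated correlation), and their adjusted p was 0.119 and 0.0977 without cerebrum 1 and 2 and 0.222 without cerebellum 3. Wnt genes were lower (0 of 13, 0 over the list alone, camera adjusted p = 0.0090, or adjusted p = 0.585 with an estimated correlation), and their adjusted p was 0.089 without cerebrum 2 and 0.119 without cerebellum 3. Microglia and macrophage genes were lower (1 of 19, 1 over the list alone, camera adjusted p = 0.0054, or adjusted p = 0.585 with an estimated correlation), and their adjusted p was 0.0923 without cerebellum 2. Venous endothelial genes (adjusted p = 0.082) passed with the block (0.0084), without cerebrum 1 (0.0347) and without cerebellum 3 (0.0099). Of 11243 genes 238 differed (200 higher in cerebellum, 38 lower), 135 with the array number as a block, and 21.7% did not overlap where chance gives 10%. The count was 44, 90 and 89 without cerebrum 1, 2 and 3, and 24 and 12 without cerebellum 2 and 3. It was 58 without the expression filter, 151 with the stricter one and 89 without the array holding pituitary transcripts.

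In the R26P model region differences passed in the controls and not in the mutants, which does not show that they are absent there, and the direct test of that change is the one that passed for 13 genes. In controls the dendrite gene Ddn was lower in cerebellum (5.77 against 2.19, adjusted p = 2.5e-04), as were the forebrain RNA Pantr1 (log2 difference −2.52, adjusted p = 3.1e-04), Alx1 (−3.04, adjusted p = 0.0097) and the secretory granule gene Chga (−3.81, adjusted p = 0.011), while Gabra6 was higher. The lower groups of Ddn, Alx1, Chga and Gabra6 lie at or near the lowest value, so the sizes depend on the background correction. Chga is also a pituitary gene, and control cerebrum 2 and 3 held pituitary transcripts. These 5 calls held whichever array was left out. Of 11243 genes 132 differed in controls (100 higher in cerebellum, 32 lower), 475 with the array number as a block, and 8.12% did not overlap where chance gives 2.86%. The count was 58, 54 and 60 without control cerebrum 1, 3 and 4, 59, 66 and 48 without control cerebellum 1, 2 and 4. It was 24 without the arrays holding pituitary transcripts, 47 without the expression filter and 68 with the mean of probe sets. In mutants limma called 0 genes, with 621 at an unadjusted p below 0.05 where chance gives 562, 2.77% without overlap, and 0 again with the array number as a block or with an intensity trend and robust prior. No other tool was run. The count was 42 without mutant cerebrum 3 and 1 without mutant cerebellum 3. For some genes the regions still differed in the single mutant pairs, but in pair 3 Gabra6 was not higher in cerebellum (2.39 in cerebrum, 2.21 in cerebellum). Gria4 read 3.16, 3.23, 3.23 and 3.16 in cerebrum 1 to 4 and 5.40, 3.52, 3.19 and 3.51 in cerebellum, so that pairs 2 to 4 all stayed near its background. The region of its 2 arrays is not settled, which limits what the 0 shows. Ddn read 5.86, 5.53, 5.10 and 6.05 in cerebrum against 2.16, 2.17, 3.56 and 2.21 in cerebellum (log2 difference −3.11, adjusted p = 0.382), a difference that passed without mutant cerebrum 3 or without mutant cerebellum 3 (lowest adjusted p = 0.028). Its difference between genotypes did not pass (0.46, adjusted p = 1). The mean of the pericyte list was higher in cerebellum in each of the 4 pairs (8.53, 8.74, 8.43 and 7.50 against 7.56, 7.60, 8.23 and 6.81), as was that of the immediate early and heat shock list, and these lists were not tested in this comparison.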

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

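All tests of the pituitary pattern in this part, and leaving arrays out for the pattern, were chosen after the values had been seen, whereas the rule for distant arrays, the differences of effects and the splits of arrays were set beforehand.

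Signals of Gh, Prl and Cga mark arrays rather than genotypes. Gh stood at 2.84 in ret mutant 3 against 13.68 to 15.23 in the other 3 ret mutants, and Plvap followed with 10.41 against 12.24 to 12.85. A candidate explanation is pituitary tissue carried along with the vessel fragments, and 9 of 9 arrays with Gh above 8 also had Prl and Cga above 8, against 1 of the 21 other arrays with either. The ret genotype as the source of Gh is argued against by 3 of 18 control or wild-type arrays with Gh above 8 (control cerebrum 2 and 3, wild-type cerebrum 3); among ret arrays it was 3 of 4 mutants and 0 of 4 controls (Fisher's exact test, two-sided p = 0.143). Pomc, another pituitary gene, did rise in ret mutants (log2 change 3.23 ± 0.59 (SE), adjusted p = 0.0103). It read 11.65 in ret mutant 3, which lacks the other 3 transcripts, against 9.30 to 10.20 in ret controls, so its rise is not explained by those arrays alone. Its change was 1.80 with the pituitary covariate and no longer passed. How such tissue came to be on some arrays was not tested.

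Each group of 4 arrays was searched for an array far from the other 3, by the gap to the nearest array as a share of the range, in 264 groups of named genes with signal above 4 and 153 groups of list means. Because the gap is measured against the range, a marked array can lie close to the others in log2 units. Chance marks about 1 group in 20. In all 21 gene groups and 7 list groups were marked, the latter no more than chance gives. In ret controls these were Dll1 at 9.85 in array 1 (others 8.82 to 8.95), Tfrc at 13.62 in array 3 (13.99 to 14.03), Ccr6 at 5.99 in array 4 (2.16 in the others), Plac8 at 4.50 in array 1 (2.77 to 2.78) and the Wnt list at 11.50 in array 3 (11.66 to 11.68). Xist at 2.32 and Eif2s3y at 9.49 marked ret control 4, and Xist at 2.32 and Eif2s3y at 9.43 marked ret mutant 1, the array of the other sex in each group. In ret mutants they were also Eng at 14.32 in array 4 (14.56 to 14.57), Cdh26 at 11.99 in array 4 (12.47 to 12.55), Mmrn1 at 5.31 in array 3 (7.47 to 7.72), the leukocyte adhesion and activation list at 10.08 in array 3 (9.71 to 9.77) and the acute phase and complement list at 9.88 in array 3 (8.75 to 8.86).

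The R26P groups held further arrays that this rule marked. Pdgfb read 7.51 in mutant cerebellum 3 (others 4.73 to 5.02) and Cd248 read 4.61 in mutant cerebrum 3 (3.02 to 3.22), and the PDGF signalling list was at 9.36 in mutant cerebrum 3 (8.75 to 8.80). Array number 3 had the highest Pdgfb signal of the mutants in both regions, with 8.01 in cerebrum. Control cerebrum 2 stood out for Notch3 (12.23 against 12.10 to 12.11) and 5033404E19Rik (7.67 against 8.70 to 8.82), and control cerebrum 1 for Gbp2 (12.46 against 12.93 to 13.02). Control cerebellum 2 stood out for Slc6a13 (7.74 against 6.49 to 6.70) and control cerebellum 1 for Pantr1 (4.17 against 4.36 to 4.37). The junctions list was at 11.58 in mutant cerebellum 4 (11.71 to 11.74), the TGF-beta and BMP list at 11.87 in the same array (11.76 to 11.77), and the venous endothelial list at 12.07 in mutant cerebrum 4 (11.32 to 11.42). Plac8 read 11.28 in mutant cerebrum 4 (8.34 to 8.82), and Gria4 read 5.40 in mutant cerebellum 1 (3.19 to 3.52). No explanation was tested for these arrays.

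Tests of differences between effects passed for 10 named genes. Between the cerebellum and cerebrum of R26P mutants the log2 effects differed by 2.89 for Alx1, 2.12 for St6galnac5, 1.77 for Pantr1, −2.57 for Ebf2 and −1.67 for St8sia1. Pantr1 apart, controls of the other region already lay at or near the lowest value, and for Pantr1 (4.17 to 4.37 in control cerebellum) background is not excluded. Between ret mutants and R26P mutant cerebrum they differed by 7.00 for Pdgfb, 7.31 for Ccr6, 4.73 for Mmrn1, 3.63 for Dcdc2a and 3.56 for Cpxm2. Ccr6 also varied between cohorts, with a group mean near the lowest value in R26P mutants. Mmrn1 lay at or near that value in ret controls and in R26P control and mutant cerebrum.

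Other splits of the same arrays into groups of the same sizes were fitted to see whether chance can be excluded. It can for ret mutants (1870 genes, highest of the other splits 3, 1 of 35 splits as large, the real one included). It can also for R26P cerebrum (2097 against 30, 1 of 35) and R26P cerebellum (1758 against 18, 1 of 35). For the regional difference of the R26P effect the counts were 13 against 0 (1 of 35). There the other splits mix mutants with controls, which adds the genotype effect to the spread within groups. Low counts can then arise whether or not the regions differ, so these splits do not tell. For wild-type regions the 10 splits are too few for a share under 0.05 (238 against at most 1). For R26P controls 2 of 35 splits gave as many as 132, so chance is not excluded over all splits. The larger one, with 262 genes, sets animals 1 and 2 against 3 and 4 and parts no pair of regions, and among the 8 splits that part every pair the highest other count was 0. For R26P mutants all 35 splits reached the real 0. The highest count was 100, for animals 1 and 2 against 3 and 4, which points to differences between animals. A split with 82 genes, however, parts 2 pairs of regions, so it is not a contrast between animals alone. For the difference between models 5 of 100 drawn splits were as large as 377, up to 1496, but the larger draws keep few mutants in the ret part and most in the R26P part. They add up the effects of both cohorts and point to the structure of the arrays, so these draws do not tell whether chance can be excluded.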

How the results depend on the processing

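The alternatives with the pituitary transcripts or Xist, and the fits of lists and correlations without single arrays, were chosen after the results had been seen, and the others beforehand. The cause of a shift was not tested unless the alternative's construction shows it (more or fewer genes or arrays).

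For ret mutants the 1870 genes became 1229 without a filter, 2924 when all probe sets were counted, 987 with a replicate block, 1051 with the sex label (which Xist contradicts on the 4 controls; 1744 with the Xist level, 1650 of them among the 1870), 892 with the pituitary covariate (713 of them among the 1870) and 919 without the pituitary-positive arrays (617 among them). For R26P cerebrum the 2097 became 1390 without a filter, 3245 in a fit of all 30 arrays, 1278 with the block and 237 without the pituitary-positive arrays. For cerebellum the 1758 became 1081 without a filter, 2698 in the fit of all arrays, 1133 with the pituitary covariate and 1117 without the array. The shared 546 became 279 without a filter.

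The 13 genes of the regional difference became 6 without a filter, 0 with the stricter filter, 4 with the mean of probe sets, 45 with the block, 29 as differences per number and 7 without the pituitary-positive arrays. The 377 of the difference between models became 177 without a filter, 102 with the pituitary covariate and 130 without the arrays. Wild-type regions went from 238 to 58 without a filter, 151 with the stricter one, 64 in the fit of all arrays, 135 with the block and 89 without the array. R26P control regions went from 132 to 47 without a filter, 68 with the mean of probe sets, 275 in the fit of all arrays, 475 with the block and 24 without the arrays. R26P mutant regions went from 0 to 1 without a filter, 27 in the fit of all arrays and 1 without the arrays.

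With an estimated correlation 0 lists were called in each of the 4 comparisons. With fry 10 lists were called in R26P cerebrum and 6 in wild type. In ret mutants fry also called the sprouting, TGF-beta and BMP, PDGF signalling and oligodendrocyte lists, which camera did not. It did not call the smooth muscle and microglia lists (fry adjusted p = 0.119 each), which camera did. The sprouting list passed fry in R26P cerebellum too (adjusted p = 0.0047). Fry did not call the microglia and macrophage list there (adjusted p = 0.156), which camera did. The same held for the choroid plexus and ependyma (0.124) and the immediate early and heat shock list (0.0598). In wild type fry did not call the smooth muscle, basement membrane, astrocyte, barrier transporter, Wnt and microglia lists (adjusted p = 0.0742 or more), which camera did. Leaving out single arrays gave 1153 to 1931 genes in ret, 1387 to 1945 in cerebrum, 1117 to 1572 in cerebellum, 6 to 14 for the regional difference, 127 to 611 between models, 12 to 159 in wild type, 48 to 193 in R26P controls, 0 to 42 in R26P mutants and 397 to 651 shared genes. The correlation between models ranged from 0.521 to 0.659, and lists from 6 to 8 in ret, 10 to 15 in cerebrum, 12 to 13 in cerebellum and 9 to 11 in wild type.

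Of the named log2 changes, 1 was counted as reversed: Plvap in ret mutants, −0.53 without the pituitary-positive arrays, which leaves 1 mutant. Changes that did not pass and switched sign without passing were not counted. Leaving out those arrays ended the call of 39 of 158 named changes, with fewer arrays in each test. Renewed quantile normalization left 158 of 158 named changes on their side of the threshold, and it moved the share of lower genes from 55.2% to 48.1% in R26P cerebrum and from 55.6% to 47.8% in cerebellum. Other probe sets of the named genes lost the call in 12 of 71 cases, and leaving out an array in 28 of 1342. Calls were also lost in 5 of 153 cases with the replicate block, 8 of 158 without the filter and 7 of 145 with the pituitary covariate. Signals near the background limit the size, more than the direction, of the largest changes. The tests of R26P controls against wild type, and wild type as the control of R26P mutants, were not run.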

Other observations

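The tests of the leukocyte genes, of endothelial enrichment and of brain tissue were chosen after the results had been seen, and those of the pituitary and Xist covariates were written before their results.

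A set of 15 transcripts of monocytes and other blood leukocytes was chosen after values had been seen and was not tested as a list. Of its 13 measured genes 10 rose in ret mutants (median log2 change 2.72), 6 rose and 1 fell in R26P cerebrum (2.4) and 1 rose in cerebellum (1.30). Plac8, a gene of myeloid cells, changed by 5.90 in ret, 5.16 in cerebrum and 2.59 in cerebellum, where it did not pass. The integrin Itgal changed by 2.75, 3.40 and 2.35, again without passing in cerebellum. Control signals of Itgal, and of Plac8 in ret, lie near the lowest value, so these sizes depend on the background. The receptor Treml4, of patrolling monocytes and spleen macrophages, rose by 4.13, 4.96 and 3.86, the last a call (adjusted p = 0.045) that ended, with an adjusted p of up to 0.112, without any array other than mutant cerebellum 2. Its signals in ret and R26P controls, 2.16 to 2.76, lie at or near the lowest value, so these sizes depend on the background too. The classical monocyte receptor Ccr2 did not pass in ret (log2 change 0.03). No test separated cells in the vessel lumen from cells in the wall, and no explanation was tested.

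The genes that rose in all 3 mutant comparisons are 227, fewer than the 319 that fell, with median log2 changes of 1.15 in ret, 1.12 in R26P cerebrum and 1.01 in cerebellum. A higher share of endothelial RNA after the loss of mural RNA was not excluded as a cause. These medians exceed those of the pan-endothelial list (−0.06, 0.18 and 0.27) by at least 0.73, beyond the spread of that list (SD 0.40, 0.36 and 0.36). The genes were chosen for being higher in these same fits and the list was not, so a gap can arise whatever the cause. The list medians show only how far endothelial genes moved in general. At least a share of 1.00 of the median was kept with the pituitary transcripts as a covariate in ret and R26P cerebrum, the comparisons tested (in cerebellum the median was 0.96 with it). In cerebrum, control and mutant arrays 2 and 3 alike hold these transcripts, so the covariate could hardly lower the median. In ret the median was 1.34 with it, a value that rests on ret mutant 3, the mutant array without them. With Xist a share of at least 1.01 was kept. By Xist the ret groups are balanced for sex, so that covariate could not lower the median there, and the balance itself argues against unequal sex in ret. R26P controls (1 male of 4) and mutants (2 of 4) are nearly balanced, so their fits decide little. A response of endothelial cells to missing pericytes may stay as a hypothesis, and age, background and developmental loss of pericytes were not tested.

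Astrocyte genes fell as a list in each of the 3 mutant comparisons with the preset correlation, and none passed with an estimated one (adjusted p = 0.305, adjusted p = 0.169 and adjusted p = 0.407 with an estimated correlation). Less brain tissue of every kind on the vessels would lower all brain cell lists alike. In ret mutants the oligodendrocyte median lay 1.11 above that of the astrocyte list, beyond the spread of both (SD 0.53 and 0.71). Yet 2 of its 8 measured genes fell, none rose, and fry called the list lower (adjusted p = 0.0333). Its members Mog, Mag, Ermn, Opalin and Olig2 lay under the expression filter. The fragments may thus have held little oligodendrocyte RNA to lose, so the gap does not exclude less brain tissue. The microglia median lay 1.78 above the astrocyte median, but blood leukocyte transcripts rose on the same arrays, so that gap does not measure brain tissue alone. In R26P mutants only the oligodendrocyte list, with 8 of 16 genes measured, lay above the astrocyte list beyond the spread in both regions. Its medians (−0.02 in cerebrum, 0.20 in cerebellum) lay at least 1.47 above those of astrocytes, beyond the spread of both lists (SD 0.71 and 1.11 in cerebrum). With the same members unmeasured, this gap does not exclude less brain tissue either. The microglia medians fell with the astrocyte list there (−0.65 in each region). A joint loss of astrocyte and neuron material stays open in R26P mutants, where the neuron medians of −0.72 and −0.82 lay 0.77 and 0.83 above those of astrocytes, within the spread. A first form of this test, which asked all 3 lists to lie above beyond their spread, left the R26P case undecided and was replaced after its result was seen. Weaker hold of astrocyte end-feet on vessels without pericytes could be a source in both models, a hypothesis that was not tested.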
